A study of Mus musculus with 8 samples.

How the data were processed

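The series holds 8 mouse samples, and 2 of them, single-cell RNA libraries of day 5 embryoid body cells labelled wild type (WT) and Tet triple knockout (TKO), had a processed file and were analysed. The other 6, pull-downs of 5-hydroxymethylcytosine from wild-type cells at days 0, 2 and 5 with 2 samples per day, were not analysed here. Groups came from the genotype and day in the labels, with 1 library per group.

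The authors deposited raw counts per gene and cell for each library, which are whole numbers that were read here as counts of unique molecular identifiers (UMIs), and no cell annotation was used. Seurat 3 and the mouse build mm10 are named in the submitters' processing notes without their role, and the notes also list BSMAP, MACS2 and DESeq2, which may belong to other data types of the series. The aligner, the counting tool, the single-cell chemistry and any filter applied before deposit are not given in the sources used here. No cell in the deposited counts had fewer than 644 genes or 2396 UMIs, so low-count barcodes were absent from both tables. The counts covered 27998 gene rows in each library, of which 26709 carried a symbol found in the gene name table supplied with the data. The WT-labelled table held 4395 cells. The TKO-labelled table named 3224 barcodes in its header but held 3223 values in each row, so its cells were read by position and barcode names were not used. In 116 row names the TKO-labelled table had an ending of -2 where the WT-labelled table had -1, with all other names in the same order. Rows were therefore matched by position and named as in the WT-labelled table, and log2 totals then correlated at 0.971 across genes, which are not independent replicates. Rows that shared a symbol, 56 symbols in all, were kept apart. The totals before filters were 37537946 UMIs in the WT-labelled library and 33602635 in the TKO-labelled library.

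Cells were kept with at least 500 genes, at least 1000 UMIs and a mitochondrial share of at most 15%. The gene and UMI minimums removed no cell, and the mitochondrial limit removed 3 WT-labelled and 26 TKO-labelled cells. Doublets were marked per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. It marked 12 WT-labelled cells (0.27%) and 7 TKO-labelled cells (0.22%), so the caller is taken not to have worked, and doublets remain in the data beyond those removed. This left 4380 WT-labelled cells with 37374085 UMIs and 3190 TKO-labelled cells with 33377913 UMIs.

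Counts were summed over kept cells and divided by the library total and scaled to a common total to give CPM, with exact Poisson 95% intervals. The ratio of the libraries was given with an exact 95% interval from the binomial share of the summed counts. Shares of cells have exact Clopper-Pearson 95% intervals. These intervals cover counting error only. A gene at 0 in 1 library was set to a floor of 3 counts, worth 0.0803 CPM in the WT-labelled and 0.0899 in the TKO-labelled library, and its ratio was given as a bound. With 1 library per group no test across libraries was possible, so no p-value is given and no number of differing genes is reported over the whole transcriptome.

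Before the data were examined, 38 gene lists were fixed, 17 of cell type markers and 21 of pathways and other gene groups. For each list the median log2 ratio was taken over members with at least 10 UMIs in both libraries together, with a prior count of 0.5, and set as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The range of a list median was read from the ranks of its members and is not a counting interval, and for 8 members it runs from the lowest to the highest. For Hox genes within endothelial-like cells a counting interval of the median was added after seeing the data, from 10000 draws of gamma rates with each count plus 0.5 as shape. The percentile describes these libraries and is not a test. A median of all 15342 genes with at least 10 UMIs of 0.14 is the reference point for list medians. The rule for named genes was also fixed in advance. Over the whole library it took the 12 highest and 12 lowest ratios among genes with at least 50 CPM in the higher library, without mitochondrially encoded genes, ribosomal protein genes and gene models named Gm or Rik. From each list it took up to 3 members at either end among those with at least 20 UMIs, and any member of the cardiac progenitor list and of the Tet and DNA methylation list. Within a class it took 6 genes at either end.

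For clustering, cells of both libraries were normalised to 10000 UMIs and log-transformed together, without integration. From 2000 variable genes chosen within each library, 30 components were computed, and 15 nearest neighbours were joined in a graph weighted by shared neighbours, which was split with the Leiden method in igraph 0.11.9 at resolution 0.8. A cluster was named only if at least 3 members of a fixed marker list were among its 10 leading genes and at least 3 members were seen in 10% or more of its cells. The markers were fixed in advance and this naming rule was set after the clusters had been seen. Gene levels were compared within a class with at least 50 cells of each library. Shares of cells with a UMI and cell cycle phases were computed after each cell was thinned to 4000 UMIs, the 10th percentile of the shallower library rounded down to a multiple of 500. The genes shown in thinned cells, the count of cells with 3 or more contractile genes, and the classes used as background were chosen after the data had been seen.

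Alternatives fixed in advance were no cell filter, a strict filter of at least 2000 genes and at most 5% mitochondrial UMIs, doublets kept, TMM factors from edgeR 4.0.16, a total without mitochondrial and ribosomal protein genes, equal weight for each cell, other expression and count minimums, a floor in place of the prior count, Leiden resolutions of 0.4 and 1.2, clustering without the genes that differ 2-fold or more between the libraries, clustering of each library on its own, and no thinning. Alternatives added after seeing the data were removal of the 6% of cells with the highest doublet scores, omission of blood-like cells, omission of a low-UMI cluster and of clusters low in mitochondrial UMIs, and a comparison of cardiomyocyte-like cells clustered per library. The summary of the whole-library comparison under alternatives, how many named genes stay named, was also chosen after seeing the data.

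The ratio, its interval and the list percentile were tested on simulated counts for the comparison of the TKO-labelled with the WT-labelled library, over 15342 genes with 200 of them changed. The 95% intervals held the true ratio for 95.7% of unchanged genes, and for 100%, 96%, 94% and 94% of genes with true ratios of 0.25, 0.5, 2 and 4. Of 200 lists of 14 unchanged genes, 5.5% lay below percentile 2.5 or above 97.5. Counts were drawn independently for each gene from Poisson rates, the model behind the intervals, so the simulation checks the computation only. Variation between cells or cultures and genes that vary together were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and R 4.3.3. Figures were drawn with matplotlib 3.10.9.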

Results

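The data came from a mouse embryonic stem cell line of the E14 background that carries a green fluorescent reporter for Nkx2-5, a cardiac transcription factor gene. Cells were kept on mitomycin-treated embryonic fibroblast feeders and then differentiated without leukemia inhibitory factor as embryoid bodies, aggregates formed in hanging drops. Of the 8 samples, 6 were pull-downs of 5-hydroxymethylcytosine, the oxidised base that TET enzymes make from 5-methylcytosine, and were not analysed here. The other 2 were single-cell RNA libraries of day 5, 1 labelled wild type (WT) and 1 labelled Tet triple knockout (TKO), and they address how the loss of TET proteins alters the cells formed on the way to the cardiac lineage. The WT-labelled library held 4380 kept cells and 37374085 UMIs, with a median of 7842.5 UMIs and 2431 genes per cell. The TKO-labelled library held 3190 kept cells and 33377913 UMIs, with a median of 9665 UMIs and 2842.5 genes per cell. Median mitochondrial shares were 3.44% and 4.05%, and median ribosomal protein shares 31.2% and 30.3%, in that order. Each group had 1 library, so there is no replicate check, a difference between the libraries cannot be separated from a difference between cultures or preparations, and the ranges in brackets, unless said otherwise, are 95% intervals for counting error only.

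Transcripts of all 3 targeted genes were counted in the library labelled TKO. Tet1 stood at 12.4 CPM (UMI counts scaled to a common library total) in the WT-labelled library (462 UMIs) and 22.8 in the TKO-labelled library (760 UMIs), a ratio of 1.84 (1.64 to 2.07). Tet2 stood at 6.82 (255 UMIs) and 4.61 (154 UMIs), a ratio of 0.676 (0.550 to 0.829), and Tet3 at 29.1 (1087 UMIs) and 20.2 (675 UMIs), a ratio of 0.695 (0.631 to 0.766). The deleted part of each gene is not given in the labels, and transcript tags outside it check nothing, so these levels do not test the labels and the libraries are named by them throughout. Among other genes of DNA methylation, Dnmt3b, a de novo methyltransferase of early embryonic cells, was 7.85-fold higher (7.30 to 8.45) in the TKO-labelled library. Zfp57, which protects imprints, was 2.42-fold higher in the WT-labelled library (2.08 to 2.83), and the maintenance methyltransferase Dnmt1 stood at 55.1 and 55.3 CPM. The Tet and DNA methylation list had a median log2 ratio of 0.31 over 14 members, 11 of them higher in the TKO-labelled library, at percentile 93.45 of random lists.

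Over the whole library, the genes lowest in the TKO-labelled library were led by genes of connective tissue and blood. They included Wisp1, Col1a1, Tac2, Upk3b, Col1a2, Postn, Col3a1, Lum, Acta2, Pitx1 and Hbb-y. Col1a1, a chain of type I collagen, stood at 152 CPM in the WT-labelled and 0.2996 in the TKO-labelled library, and was 508-fold higher in the former (276 to 1060). Postn, the matrix protein periostin, was 334-fold higher in the WT-labelled library (233 to 499), and Acta2, smooth muscle actin, 71.6-fold higher (64.5 to 79.7). The highest in the TKO-labelled library were Otx2, Trh, Pim2, Sall1, Cdh1, Pou5f1, Pla2g1b, Cldn6, Epcam, Emb, Fmr1nb and Cyp26a1, which include genes of pluripotent and epithelial cells. Otx2, a transcription factor of the epiblast and the anterior embryo, was 112-fold higher (79.6 to 163), and Pou5f1, which encodes the pluripotency factor Oct4, 11.8-fold higher (10.5 to 13.3). Trh, which encodes thyrotropin-releasing hormone, stood at 6.90 and 529 CPM. All 24 genes that the rule picked kept their direction under every alternative in which they were recomputed. They were picked as the extremes, the least of them Cyp26a1 at 9.13-fold, so a kept direction says little about robustness. Which genes were named depended on the expression minimum, with 2 of the 12 highest and 6 of the 12 lowest still named at a minimum of 10 CPM.

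Genes of the cardiac contractile apparatus were mostly higher in the TKO-labelled library. The contractile list had a median log2 ratio of 1.98 over 13 members, 12 of them higher in the TKO-labelled library, at percentile 100 of random lists. Myh7, a cardiac myosin heavy chain, was 6.15-fold higher (4.58 to 8.40) and Myh6, another, 10.3-fold higher (4.11 to 33.2) on 5 and 46 UMIs. Tnni1, a slow troponin I, was the exception, at 191 CPM in the WT-labelled and 129 in the TKO-labelled library, while the ratio of Actc1 was 1.03 (0.843 to 1.26). Tnnt2 and Myl7, named after their values were seen, were 3.10-fold (2.87 to 3.35) and 4.03-fold (3.75 to 4.33) higher in the TKO-labelled library.

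Cardiac progenitor genes did not go together in 1 direction. Of 16 members, 7 were higher and 9 lower in the TKO-labelled library, with a median log2 ratio of -0.40 at percentile 0.14 of random lists. Hand1, a transcription factor of cardiac and extraembryonic mesoderm, stood at 634 CPM in the WT-labelled and 46.1 in the TKO-labelled library, a difference of 13.8-fold (13.1 to 14.5). Bmp4 and Tbx20 were also higher in the WT-labelled library, 3.12-fold (2.94 to 3.31) and 2.75-fold (2.497 to 3.04), as were Tbx5, a factor of the first heart field, 1.84-fold (1.37 to 2.47), and Hand2, 1.68-fold (1.58 to 1.78). In the other direction stood Isl1, a marker of second heart field progenitors, 6.77-fold higher in the TKO-labelled library (6.17 to 7.45), Mesp1 of early cardiac mesoderm, 6.80-fold (4.51 to 10.6), Nkx2-5, 4.13-fold (3.39 to 5.06), and Mef2c, 3.85-fold (3.62 to 4.09). The interval of Gata4 reached from 0.977 to 1.23 and that of Hcn4, on 22 and 14 UMIs, from 0.337 to 1.46, so neither difference was detectable at this depth.

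**Figure D1:**
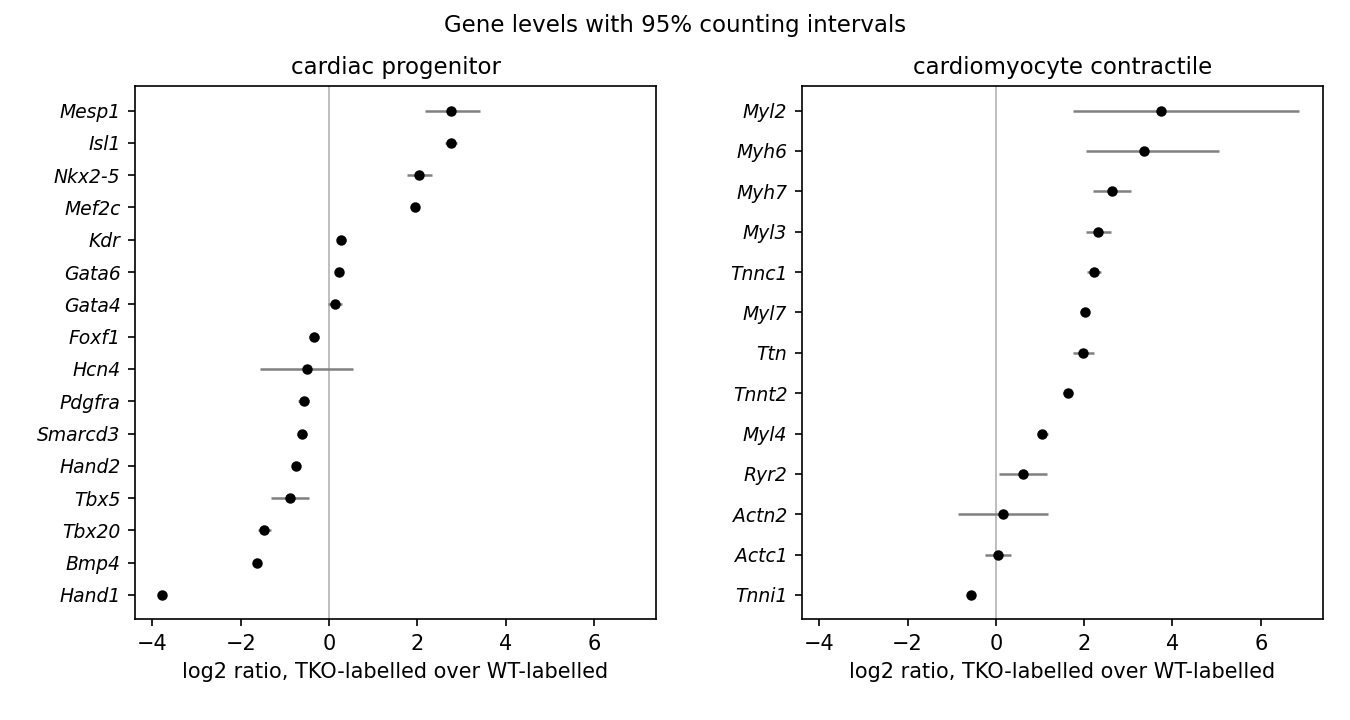
Log2 ratio of CPM, TKO-labelled over WT-labelled library, for each member of the cardiac progenitor list (left) and of the contractile list (right), with 95% counting intervals as bars. Progenitor genes lie on both sides of 0, from Hand1 to Mesp1, and 12 of 13 contractile genes lie to the right of 0.

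At equal depth, more cells of the TKO-labelled library held several contractile genes, though not every such gene was seen in more cells. After thinning to 4000 UMIs, which left out 372 WT-labelled and 190 TKO-labelled cells as too shallow, 1.55% of 4008 WT-labelled cells (1.19 to 1.98) and 8.90% of 3000 TKO-labelled cells (7.91 to 9.98) held at least 3 contractile genes. Without thinning these shares were 4.00% and 15.6%. Endothelial-like cells, which should lack these genes, gave 0 of 161 in the WT-labelled and 0 of 65 in the TKO-labelled library, which allows shares of up to 2.27% and 5.52%, and definitive endoderm-like cells gave 0 of 32 and 11 of 897 (1.23%, up to 2.18%). Median depth before thinning was 7888 and 11846 UMIs in endothelial-like cells and 8054 and 10713 UMIs in definitive endoderm-like cells, against 8168.5 and 9988 UMIs for all thinned cells. Tnnt2 was seen in 6.46% of WT-labelled cells (5.72 to 7.27) and 11.2% of TKO-labelled cells (10.1 to 12.4), with 12.1% and 16.1% before thinning and 0% and 4.62% in endothelial-like cells. Actc1 showed no detectable difference, at 1.10% (0.799 to 1.47) and 1.27% (0.898 to 1.73), with 2.08% and 2.48% before thinning and 0.621% and 0% in endothelial-like cells. In definitive endoderm-like cells its shares were 6.25% (2 of 32) and 1.34% (12 of 897), so the library shares did not stand above that background. For Nkx2-5 the shares were 1.12% and 4.77%, with 1.58% and 8.53% before thinning, 1.86% and 1.54% in endothelial-like cells, and 15.6% (5 of 32) and 2.90% (26 of 897) in definitive endoderm-like cells. Isl1 was seen in 4.07% of WT-labelled cells (3.48 to 4.73) and 26.4% of TKO-labelled cells (24.9 to 28.1), with 6.51% and 43.9% before thinning. Its shares were 8.08% and 9.23% in endothelial-like cells and 28.1% (9 of 32) and 29.9% (268 of 897) in definitive endoderm-like cells, so they are not read as shares of cardiac progenitors. Hand1 went the other way, in 74.2% of WT-labelled cells (72.8 to 75.6) and 7.03% of TKO-labelled cells (6.14 to 8.01), with 80.0% and 9.12% before thinning and 13.0% and 1.54% in endothelial-like cells.

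Core pluripotency and early germ layer genes were mostly higher in the TKO-labelled library. All 14 measured members of the core and formative pluripotency list were higher there, with a median log2 ratio of 3.46 at percentile 100, among them Fgf5, a gene of the formative epiblast, 28.2-fold (19.6 to 42.1). The naive pluripotency list had a median of 0.60 over 12 members, 8 of them higher, at percentile 97.0, but it was split, with Nanog 2.02-fold higher (1.44 to 2.85) on 56 and 101 UMIs and Klf4 1.46-fold higher in the WT-labelled library (1.36 to 1.57), as were Tfcp2l1 and Tcl1 at low counts. Primitive streak and nascent mesoderm genes had a median of 2.47 with 11 of 14 higher, at percentile 100. Gsc, a gene of the organizer, was 17.1-fold higher (11.9 to 25.5), and Mesp2, with 0 UMIs in the WT-labelled and 65 in the TKO-labelled library, was at least 24.3-fold higher, whereas Wnt3 was 2.40-fold higher in the WT-labelled library (1.81 to 3.22). Paraxial mesoderm genes had a median of 0.98 with 9 of 11 higher, at percentile 99.3, led by Foxc1, 60.1-fold (39.5 to 96.3). In the definitive endoderm list 10 of 12 members were higher, with a median of 2.79 at percentile 100, and Cer1, a secreted antagonist of the anterior endoderm, was 14.6-fold higher (9.01 to 25.0). The neuroectoderm list had the highest median of the lists with more than 2 members, 4.03 over 14 members, 13 of them higher, at percentile 100. Within it Six3, a gene of the anterior neural plate, stood at 2 UMIs in the WT-labelled and 289 in the TKO-labelled library, a ratio of 162 (44.4 to 1342).

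Mesenchymal, blood and vascular genes were higher in the WT-labelled library. The list named for feeder fibroblasts had a median log2 ratio of -5.79 over 13 members, 12 of them lower in the TKO-labelled library, at percentile 0, and the smooth muscle and mesenchyme list, which shares Acta2, Tagln and Col3a1 with it, had a median of -2.02 with 10 of 12 lower, at percentile 0. All 12 blood genes were lower in the TKO-labelled library, with a median of -3.71 at percentile 0. Hbb-bh1, an embryonic globin, stood at 4279 CPM in the WT-labelled and 118 in the TKO-labelled library. Endothelial genes had a median of -1.72 with 10 of 12 lower, at percentile 0. Tek, an angiopoietin receptor gene, was 28.9-fold higher in the WT-labelled library (20.7 to 41.7), while Etv2, an early regulator of endothelial and blood fate, was 1.66-fold higher in the TKO-labelled library (1.44 to 1.92). Tek was not confined to endothelial-like cells, since 10.15% of thinned WT-labelled cells held it while 4.27% of WT-labelled cells were endothelial-like. Within that class it was 2.44-fold higher in the WT-labelled cells (1.59 to 3.895). Extraembryonic endoderm genes had a median of -0.29 with 6 of 16 higher, at percentile 1.90, and the retinol carrier gene Rbp4 was 32.8-fold higher in the WT-labelled library (27.4 to 39.6).

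**Figure D2:**
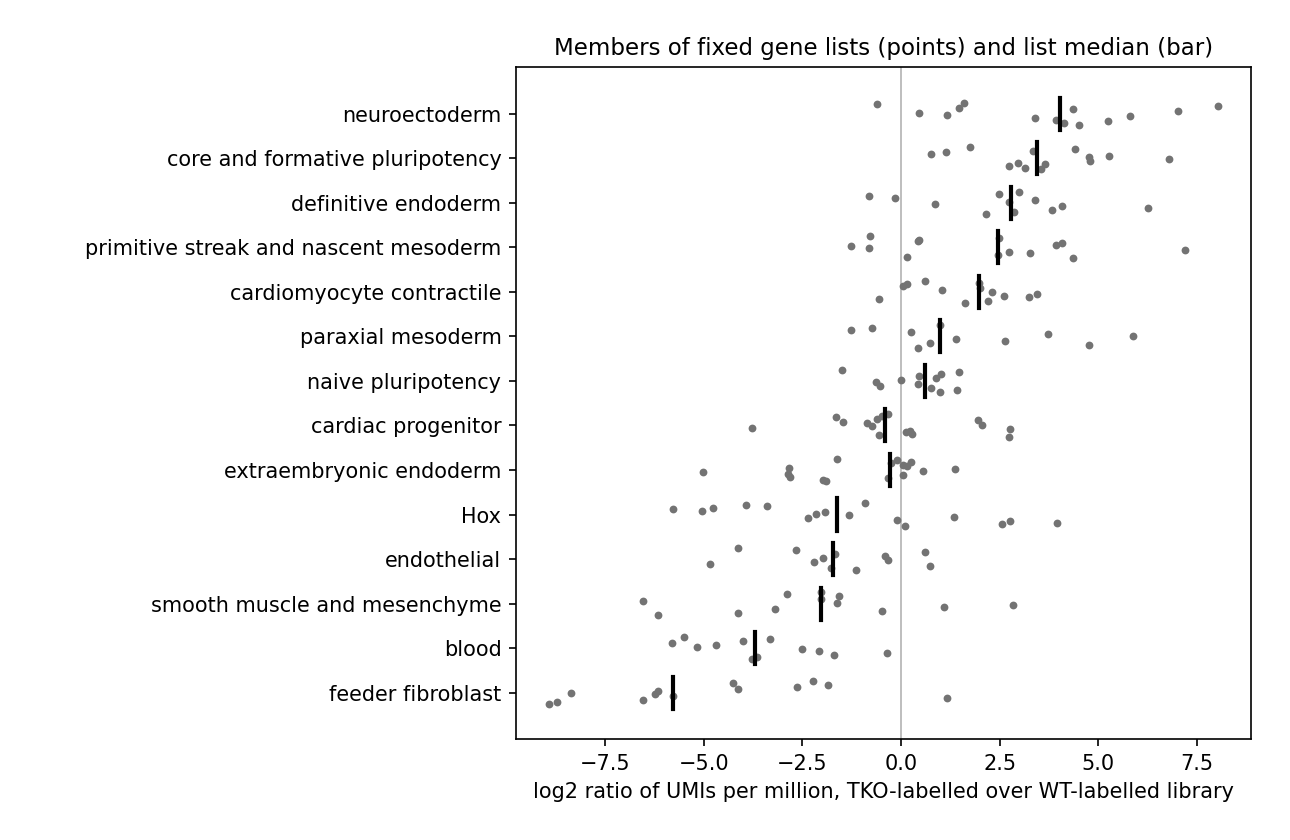
Log2 ratio of CPM, TKO-labelled over WT-labelled library, for the members of 14 fixed lists (points, spread vertically for legibility) with the list median (bar). Medians run from -5.79 for feeder fibroblast genes to 4.03 for neuroectoderm genes, and members of the cardiac progenitor and Hox lists lie on both sides of 0.

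Hox genes, which pattern the body axis, had a median log2 ratio of -1.63 over 16 members, 11 of them lower in the TKO-labelled library, at percentile 0 of random lists. Hoxb6, Hoxb5 and Hoxb8 were 56.1-fold (38.4 to 85.4), 33.9-fold (21.3 to 57.5) and 27.9-fold higher in the WT-labelled library. At low counts, Hoxa5 and Hoxa2 stood the other way, on 13 and 81 UMIs and on 6 and 34 UMIs. Imprinted genes had a median of -0.92 over 19 members, 16 of them lower in the TKO-labelled library, at percentile 0.010. Dlk1, a Notch family ligand gene expressed from the paternal allele, was 24.2-fold higher in the WT-labelled library (22.6 to 25.9) and Mest 7.54-fold (7.30 to 7.80), whereas H19 was 1.66-fold higher in the TKO-labelled library (1.32 to 2.09).

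Clusters were almost wholly split by library, so a cluster mostly of 1 library may be that library and not a cell type. Shares are given from an alternative clustering without the genes that differ 2-fold or more between the libraries, although its clusters were named from all genes. Classes stayed split there, with 1395 WT-labelled and 12 TKO-labelled fibroblast-like cells and 30 and 978 cardiomyocyte-like cells, so the same limit holds. Fibroblast-like cells made up 31.9% of WT-labelled cells (30.5 to 33.3) and 0.376% of TKO-labelled cells (0.195 to 0.656), and blood-like cells 11.4% (10.4 to 12.3) and 1.60% (1.19 to 2.10). Endothelial-like cells made up 4.29% (3.71 to 4.94) and 2.07% (1.60 to 2.63), and extraembryonic endoderm-like cells 4.13% (3.56 to 4.77) and 0.9404% (0.635 to 1.34), but the direction of the latter stays open, since the TKO-labelled library clustered on its own had an unnamed cluster of 314 cells led by Ttr and Spink1, which also led the extraembryonic endoderm-like cluster. Pluripotent-like cells came to 0.776% of the WT-labelled library (0.538 to 1.08) and 9.31% of the TKO-labelled library (8.32 to 10.4). With all genes they sat in different clusters, since a cluster with naive genes such as Zfp42 and Dppa3 held 33 WT-labelled and 20 TKO-labelled cells (0.753% and 0.627%), while another with Pou3f1 and Dnmt3b held 3 and 292. Definitive endoderm-like cells came to 0.982% (0.711 to 1.32) and 33.5% (31.8 to 35.1), and 45.9% and 21.6% of cells were in unnamed clusters. With all genes the definitive endoderm-like name rested on Trh, Cpm and Cldn6, the minimum of 3 leading markers. A cluster led by Sox17, with 4 WT-labelled and 119 TKO-labelled cells, stayed unnamed there. Cardiomyocyte-like cells came to 0.685% (0.463 to 0.976) and 30.7% (29.1 to 32.3), but the TKO-labelled share was 23.2% with all genes, 4.89% with that library clustered on its own and 0.658% at a Leiden resolution of 0.4. Of the 740 TKO-labelled cells so named with all genes, 719 were in a cluster that had 3 contractile genes among its leading genes, the minimum of the rule, and 21 in a cluster that had 7. With all genes the fibroblast-like, blood-like and extraembryonic endoderm-like shares were 30.2%, 10.96% and 4.02% in the WT-labelled library and 0.0627%, 0.596% and 0.376% in the TKO-labelled library, so the small TKO-labelled shares depended on the clustering as well, and the WT-labelled fibroblast-like share lay between 24.8% and 45.8%. No fixed share of cardiomyocyte-like cells can therefore be given for the TKO-labelled library, and the WT-labelled share lay between 0.137% and 0.845%. Definitive endoderm-like shares moved as well, between 11.8% and 33.5% in the TKO-labelled library and, with both libraries clustered together, between 0.228% and 0.982% in the WT-labelled library. Of the 480 WT-labelled blood-like cells with all genes, 66 sat in a cluster with a median doublet score of 0.3. Every other cluster had 0.093 or less, so doublets are not separated there. With the highest doublet scores removed, the WT-labelled blood-like share was 10.1%.

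**Figure D3:**
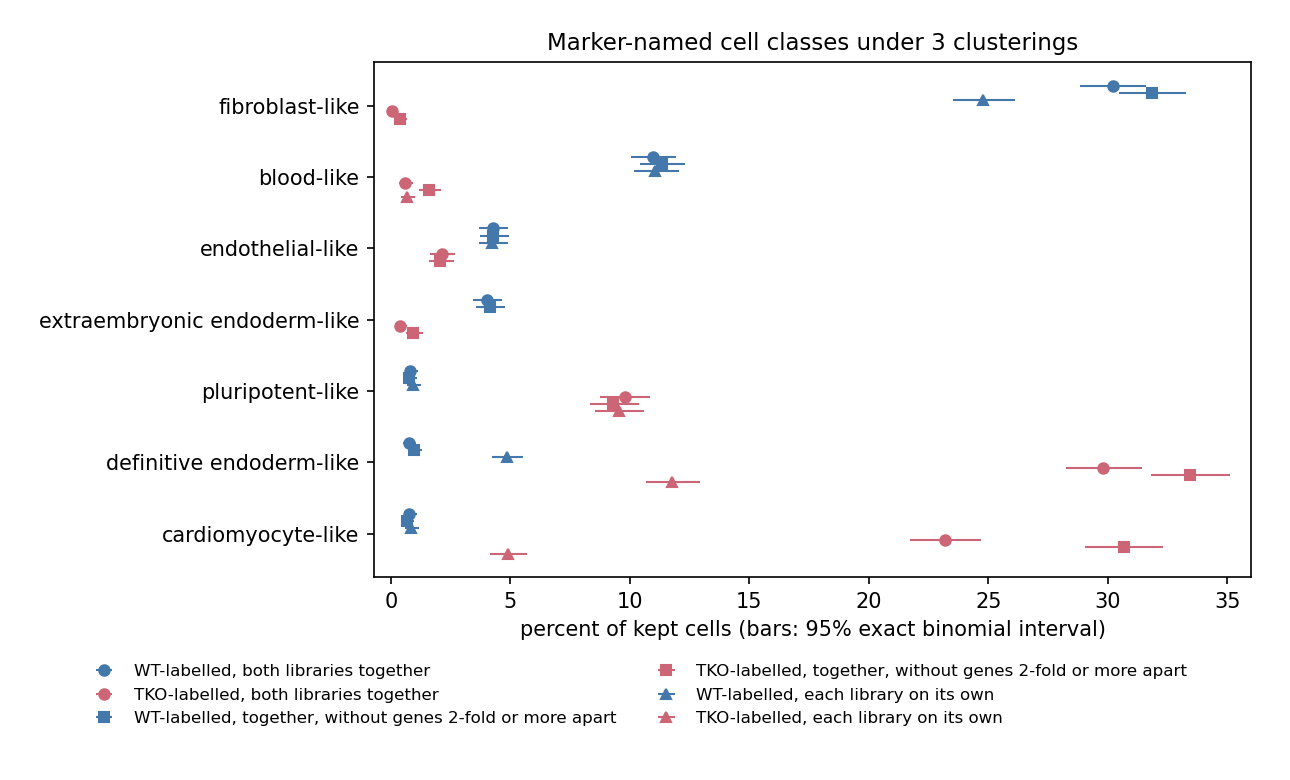
Percent of kept cells of each library in marker-named classes, with both libraries clustered together (circles), together without genes that differ 2-fold or more (squares) and each library on its own (triangles). Bars are 95% exact binomial intervals, a missing triangle marks a class that no cluster met, the WT-labelled triangle for definitive endoderm-like cells is a cluster led by genes of the extraembryonic endoderm-like cluster, and the cardiomyocyte-like and definitive endoderm-like shares of the TKO-labelled library differ most between clusterings, the former from 4.89% to 30.7%.

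In the clustering with all genes, endothelial-like cells were the only named class with at least 50 cells of each library, 187 WT-labelled and 68 TKO-labelled in 1 cluster. Endothelial markers named and led this cluster, so their levels are given only to describe its cells. Of 12 endothelial genes, 8 were lower and 4 higher in the TKO-labelled cells, with a median log2 ratio of -1.10. Pecam1 stood at 120 CPM in the WT-labelled and 10.6 in the TKO-labelled cells, and Etv2 at 82.15 and 232 CPM. All 8 measured Hox genes were lower in the TKO-labelled cells, with a median of -2.62 (-4.12 to -1.55, lowest to highest member -5.82 to -0.39), and Hoxb8 had 100 UMIs in the WT-labelled and 1 in the TKO-labelled cells. The highest in TKO-labelled cells were Apobec2, Trp53i11, Bmp2, Ptp4a3, Emb and Ebf1, among them Bmp2, a secreted growth factor gene, on 13 and 63 UMIs, a ratio between 4.90 and 17.8. The lowest were Fxyd2, Gap43, Acta2, Hbb-bh1, Nupr1 and Procr. Of these, Hbb-bh1 and Acta2 stood in WT-labelled endothelial-like cells at 11.8% and 11.2% of their level in the other WT-labelled cells, so their levels are not separated from free RNA. The same limit holds for Emb, at 137 CPM in TKO-labelled endothelial-like cells and 1036 CPM in the whole TKO-labelled library.

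Cardiomyocyte-like cells taken from a separate clustering of each library, a comparison added after seeing the data, numbered 37 in the WT-labelled and 156 in the TKO-labelled library, the former below the minimum of 50. Contractile genes led these clusters, so their levels are not compared within them. Fibroblast and mesenchyme genes were mostly higher in the WT-labelled cells. The median log2 ratio was -4.20 for the feeder fibroblast list (6 of 6 lower in the TKO-labelled cells) and -1.68 for the smooth muscle and mesenchyme list (10 of 11 lower). Hbb-bh1 had 35 UMIs against 1. Col1a1 and Col3a1 stood at 44.8 and 65.5 CPM in these WT-labelled cells, below 152 and 237 CPM in the whole WT-labelled library. Free RNA and doublets are therefore not separated from the differences of the 2 lists. Acta2, on both lists, stood at 934 and 72.6 CPM, above 764 and 10.7 CPM in the whole WT-labelled and TKO-labelled libraries. Free RNA at the library average would not reach its WT-labelled level, but doublets with mesenchymal cells are not separated from its difference. G2/M genes were also mostly lower in the TKO-labelled cells, with a median of -1.56 over 44 members while Kif20b, Anp32e and Cks1b were level, but free RNA and doublets in the 37 WT-labelled cells are not separated from this and no difference in cycling is read from it.

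By expression score after thinning, 45.1% of WT-labelled cells (43.5 to 46.6) and 43.3% of TKO-labelled cells (41.6 to 45.1) were assigned to G1, 15.4% (14.3 to 16.6) and 22.4% (21.0 to 24.0) to S, and 39.5% (38.0 to 41.1) and 34.2% (32.5 to 35.96) to G2/M. S phase genes had a median log2 ratio of 0.28 with 33 of 38 higher in the TKO-labelled library, at percentile 97.9, and G2/M genes a median of -0.11 with 16 of 52 higher, at percentile 0.21. Phase calls also read free RNA, whose share in each library is open, so no difference in cycling is read from them.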

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

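The removal of the highest doublet scores, the omission of blood-like cells or of low-UMI and low-mitochondrial clusters, and the cardiomyocyte-like comparison were chosen after seeing the data. No ratio of a named gene reversed in 192 recomputations, but these genes were picked for extreme ratios, which leaves little room for a reversal. None of 6 Tet levels moved beyond its interval. Of 459 recomputed list medians 11 took the other sign, all in the 2-cell-like, dissociation and stress, ribosomal protein and trophoblast lists. TMM factors of 0.957 and 1.05 shifted the median of all genes by -0.128, and under them the ribosomal protein median was -0.08. The contractile median lay between 1.79 (blood-like cells left out) and 2.23 (strict filter), and the Hox median between -1.78 and -1.32. The Hox median within a class was -0.73 in cardiomyocyte-like cells, over 3 members. Of 124 single-gene shares of cells, 66 moved without thinning or under the strict filter. No paired analysis was possible because the single-cell groups have 1 library each and no test, and the pull-down samples that share replicate numbers were not analysed here.

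Of the 12 lowest and 12 highest named genes, 6 and 2 were still named at a minimum of 10 CPM, and 5 of the highest at a minimum of 100, since these minimums admit or exclude genes by construction. Without thinning, 4.00% and 15.6% of WT-labelled and TKO-labelled cells held 3 or more contractile genes, G1 came to 41.2% and 39.7%, and S to 18.2% and 26.3%. That setting also returned the 372 and 190 cells too shallow to thin, and the cause was not tested.

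For class shares the cause of each move was not tested. At a Leiden resolution of 0.4, WT-labelled shares were 12.5% blood-like, 0.137% cardiomyocyte-like, 45.8% fibroblast-like and 31.4% unnamed, and TKO-labelled shares 0.658% cardiomyocyte-like, 33.5% definitive endoderm-like, 0.439% fibroblast-like and 51.4% unnamed. At 1.2, WT-labelled shares were 0.228% definitive endoderm-like, 28.0% fibroblast-like and 50.8% unnamed, and TKO-labelled shares 20.4% cardiomyocyte-like, 17.3% definitive endoderm-like, 0% fibroblast-like and 49.4% unnamed. With no filter on cells, WT-labelled shares were 26.4% fibroblast-like and 52.0% unnamed, and TKO-labelled shares 0.838% extraembryonic endoderm-like and 0% fibroblast-like. With doublets kept, fibroblast-like cells came to 28.7% of the WT-labelled and 0% of the TKO-labelled library, which held 25.7% cardiomyocyte-like, 0.876% extraembryonic endoderm-like and 31.8% unnamed cells. Without genes that differ 2-fold or more, WT-labelled shares were 31.9% fibroblast-like and 45.9% unnamed, and TKO-labelled shares 1.60% blood-like, 30.7% cardiomyocyte-like, 33.5% definitive endoderm-like, 0.9404% extraembryonic endoderm-like, 0.376% fibroblast-like and 21.6% unnamed. With the highest doublet scores removed, WT-labelled shares were 27.0% fibroblast-like and 52.5% unnamed, and TKO-labelled shares 20.6% cardiomyocyte-like, 0% fibroblast-like and 38.3% unnamed. With each library on its own, WT-labelled shares were 4.86% definitive endoderm-like, 24.8% fibroblast-like and 53.2% unnamed, and TKO-labelled shares 4.89% cardiomyocyte-like, 11.8% definitive endoderm-like and 73.2% unnamed. The WT-labelled cluster named definitive endoderm-like there was led by Ttr, Spink1 and Rbp4, as was the extraembryonic endoderm-like cluster of both libraries, so its 4.86% is not read as a definitive endoderm share. No TKO-labelled cluster was then named endothelial-like or fibroblast-like, and none in either library extraembryonic endoderm-like, so these gave no value, although unnamed TKO-labelled clusters of 314 cells led by Ttr and Spink1 and of 80 cells led by Ctla2a, Kdr and Etv2 were present. WT-labelled cardiomyocyte-like shares rest on 6 to 37 cells.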

Other observations

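Signalling genes went different ways by pathway, and all of these lists were fixed before the data were examined. FGF and ERK genes were mostly higher in the TKO-labelled library, with a median log2 ratio of 1.80 and 13 of 15 higher, at percentile 100, and the growth factor gene Fgf8 was 9.67-fold higher (8.04 to 11.7). The list named for secreted Wnt inhibitors had a median of 1.60 with 8 of 11 higher, at percentile 100. Its members were split, with Shisa2 13.9-fold higher in the TKO-labelled library (11.5 to 17.0) and Dkk2 23.0-fold higher in the WT-labelled library (10.9 to 57.9). Wnt targets and feedback genes had a median of 0.36 (percentile 87.4), with T, the streak gene brachyury, on 18 and 338 UMIs, and Wnt ligands and receptors a median of 0.38 (percentile 85.55). The Nodal and activin list had a median of 0.52 with 10 of 14 higher (percentile 97.8). The BMP list had a median of -0.41 with 5 of 14 higher (percentile 0.10), and its members parted, with Msx1 6.91-fold higher in the WT-labelled library (6.52 to 7.32) and Id1 3.24-fold higher in the TKO-labelled library (3.17 to 3.32). Notch genes had a median of 0.62 with 11 of 13 higher (percentile 98.3), led by Dll1 on 3 and 85 UMIs and Jag1 on 28 and 556 UMIs.

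Epithelial to mesenchymal genes had a median of 0.46 (percentile 99.7), with the epithelial genes Cdh1, Cldn6 and Epcam over 10-fold higher in the TKO-labelled library and Snai2, Fn1 and Vim 7.38-fold (6.77 to 8.06), 5.46-fold (5.30 to 5.63) and 3.10-fold (3.02 to 3.17) higher in the WT-labelled library. Extracellular matrix genes had a median of -0.53 with 5 of 15 higher (percentile 0.030). Medians were 1.96 for neuron genes over 8 members (percentile 100), 1.08 for surface ectoderm and epithelium (99.8), 0.88 for primordial germ cell genes (97.2), 1.47 for germline genes over 11 members (99.25), and -0.23 for trophoblast genes (11.1). The germline genes Mael and Ddx4 were 10.5-fold (5.25 to 23.7) and 26.9-fold (7.05 to 228) higher in the TKO-labelled library on at most 84 UMIs. Medians closer to that of all genes were seen for glycolysis and hypoxia (-0.17, percentile 2.82), p53 targets (0.26, 86.4), dissociation and stress (0.01, 26.2), ribosomal protein (0.05, 49.7) and mitochondrially encoded genes (0.26, 95.4), and Ndrg1, a hypoxia-responsive gene, was 13.0-fold higher in the WT-labelled library (10.6 to 16.0). The 2-cell-like list had only 2 members with enough UMIs, with a median of 2.29 (percentile 97.48), and is not read further.

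In the patterns below, the tests of swapped labels and of feeder carry-over were chosen after the results had been seen, as were the count of cells with 3 or more contractile genes, the counting interval of the Hox median and the comparison of Hox levels with free RNA. Contractile genes were higher in the TKO-labelled library, with a median log2 ratio of 1.98, whereas the title of the series names impaired differentiation toward the cardiac lineage. A difference in depth is argued against, since with every cell thinned to equal depth the Tnnt2-positive share was 1.73 times as high in the TKO-labelled library (1.47 to 2.05). Free RNA as the only source there is argued against, since cells with both Tnnt2 and Myl7 were 4.66 times as frequent as independence gives (3.91 to 5.49). The same value was 6.42 in the WT-labelled library (4.03 to 9.71), so it does not bear on the difference between the libraries. The Tnnt2 ratio takes off no background, which was 0 of 161 and 3 of 65 endothelial-like cells (4.62%, up to 12.9%), so it does not bear on free RNA. The 8.90% of TKO-labelled cells with 3 or more contractile genes (7.91 to 9.98) did lie above the upper bounds of 5.52% and 2.18% in endothelial-like and definitive endoderm-like cells. In the WT-labelled library that share was 1.55% (1.19 to 1.98). Swapped library labels cannot be told apart from a genotype difference, because the Tet1 ratio of 1.84 (1.64 to 2.07) and the other Tet levels come from transcripts whose deleted part is not known. A genotype effect, a difference in the pace of differentiation between cultures, and clone or batch effects stay open and untested with 1 library per group.

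Fibroblast genes were far higher in the WT-labelled library, where Acta2, Postn, Col3a1 and Col1a2 stood at 764, 290, 237 and 211 CPM. Mitomycin-treated feeders do not divide, while 776 cells with at least 3 Col1a1 UMIs had 1.06 times (1.05 to 1.07) the share of G2/M UMIs of the other WT-labelled cells. Free RNA enters these shares and was not taken off. The 776 cells were picked on unthinned counts, which favours deep cells, and depth was not matched. Over WT-labelled cells the G2/M share was 0.562% of UMIs without thinning and 0.529% with it. The shares argue against feeder cells carried over as the main source only if free RNA is a small part of each cell's UMIs and depth has a small effect. Of these cells 98.6% held a Hand1 UMI, but so did 80.0% of all unthinned WT-labelled cells, so Hand1 does not bear on feeders. Free RNA is argued against by cells with both Postn and Col3a1 UMIs, 1.51 times as frequent as independence gives (1.44 to 1.58), a value that barely passed the bound of 1.5 set beforehand, and by the Col1a1-positive share of 34.5% in thinned WT-labelled cells against 2.48% in endothelial-like and 9.38% (3 of 32) in definitive endoderm-like cells. The Col1a1-positive shares of fibroblast-like and blood-like cells, named beforehand as the outcome for free RNA, were not computed, and the Col1a1 levels of those cells were 223 and 25.6 CPM. A smaller number of feeder cells is not excluded, and a mesenchymal cell type formed in the embryoid bodies may account for the pattern, a hypothesis with no replicate behind it.

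Hoxb5, Hoxb6, Hoxb8, Hoxb9, Hoxc8 and Hoxa9 were lower in the TKO-labelled library, and a shift in cell classes is a candidate explanation, since the classes differ between the libraries. Within endothelial-like cells 8 Hox members were measured. They were Hoxa9, Hoxb5, Hoxb6 and Hoxb8 of those named here, with Hoxb2, Hoxb3, Hoxb4 and Hoxd1. Their median log2 ratio was -2.62 with a counting interval of -4.12 to -1.55, past the bound of -1 set beforehand. This cannot decide on a shift in cell kind, since endothelial genes also differed within the cluster. Of 12, 8 were lower and 4 higher in the TKO-labelled cells, with Pecam1 at 120 (WT-labelled) and 10.6 CPM (TKO-labelled) and Etv2 at 82.15 and 232 CPM. The 8 Hox members ran from -5.82 to -0.39, the 6 counted in both libraries had a median of -1.34 (-2.39 to -0.97), and in the few cardiomyocyte-like cells 3 members had a median of -0.73, so the size of the difference is not settled and the part played by classes stays open. Free RNA from other WT-labelled cells does not account for the WT-labelled levels, since these members stood in endothelial-like cells at 60.6% or more of their level in the whole library, and Hoxb5 and Hoxb8 at 359% and 283%, while 10 abundant genes of other cells stood at 5.35% to 14.3% of their level elsewhere. Genotype, culture, the stage reached by day 5 and a different kind of endothelial-like cell in each library stay open and untested.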
